A study of Mus musculus with 294 samples.

How the data were processed

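Liver RNA of 294 mice from an F2 intercross of the inbred strains B6/J and A/J was measured on Affymetrix expression arrays, with 1 array per animal. The deposited values are normalized intensities: the authors summarised each probe set to 1 intensity per array on a linear scale with RMA, whose version and settings the labels do not state. The table held 32640 probe sets, called probes here. The values ran from 2.77 to 25519 and the array medians from 21.1 to 23.2, so the logarithm to base 2 was taken with no pseudocount and no further scaling. The annotation gave a single gene symbol for 25508 probes, none for 7132 and several for 0. Of its 16788 symbols, 13916 were current in the mouse reference table, 2830 were updated through a synonym and 42 were left as they were. Each of the resulting 16643 genes was represented by its probe of highest mean, and the reference table was used for names and gene order only. Signal over background and the number of arrays limit the precision, and no animal was measured more than once.

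The labels place all animals in 1 group. They give no sex, and no animal was assigned to a sex or a genotype from its values. The first 3 digits of the number in each title divide the animals into 15 label blocks of 17 to 23 animals, which served as a possible batch. No array was left out of the reported values. An alternative left out 27 arrays whose median correlation with the other arrays lay more than 3 median absolute deviations below the median.

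The gene lists, the 18 relations between lists, the tests and the rule for named genes were fixed before the data were examined. The 37 lists held 496 genes, of which 416 were measured. They covered cholesterol synthesis, fatty acid synthesis, fatty acid oxidation with PPARA targets, gluconeogenesis, bile acids, xenobiotic metabolism, NRF2 targets, lipoproteins, pericentral and periportal hepatocytes, acute phase, interferon response, MHC class II, metallothioneins, ER stress, heat shock, immediate early genes, cell cycle, morning and evening clock genes, cytosolic ribosome, oxidative phosphorylation, male-biased and female-biased liver genes, Y-linked genes, genes known to differ between the parental strains, and markers of other cells and tissues. The marker lists were Kupffer cells and macrophages, T and NK cells, B and plasma cells, neutrophils, endothelium, stellate cells and fibroblasts, cholangiocytes, erythroid cells, pancreas acini, adipose tissue and skeletal muscle. The rule named the 15 genes of widest range among those above the median mean, and up to 15 genes of 1:2:1 shape with the largest gain in fit among the same genes. It also named up to 4 members of each list with the highest correlation to the rest of the list and the member with the lowest, all measured Y-linked and parental strain genes, the 5 outside genes of highest and 3 of lowest correlation with each of 5 scores, the 8 genes of largest variance share between blocks, and the 6 adjacent gene pairs of highest absolute correlation. The text leaves out some of the genes so named for length.

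The spread of a gene was the ratio of its 90th to its 10th percentile over the animals, and its SD was set against the running median SD of genes of like mean. Coexpression of a list was its mean pairwise Pearson r against 10000 random lists of the same size matched on mean, one-sided. Lists with fewer than 3 measured members were not tested. A list score was the mean z score of its members. Correlations between scores, and of genes with scores, had two-sided permutation tests with 100000 resamples for Pearson's r and Spearman's rho, and r was computed again without the 2 animals farthest from the median score. Where a score fell into clusters (a mixture of 2 normals better by a BIC of over 10, with means over 3 SD apart), r was taken within the largest cluster, a choice of cluster made after the data were seen. P-values were adjusted by the Benjamini-Hochberg method within each family at a threshold of 0.05.

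Distribution shape was assessed by maximum likelihood fits of a normal, a Student t, a skew-normal, mixtures of 2 normals and a mixture of 3 equally spaced normals with weights 1:2:1. A call needed the lowest BIC, a BIC at least 10 below the normal and adjacent means at least 1.5 SD apart. Free spacing of the 3 means was added after the data were seen. Neighbouring genes were compared by the median absolute r of adjacent pairs, leaving out pairs that share the first 3 letters of their symbols, against 1000 permutations of gene positions, one-sided. Genes with several probes were checked by the r between their 2 brightest probes. Label blocks were compared for each gene with limma's moderated F test, and 100 splits of the animals into blocks of the same sizes, the real one included, were counted.

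The alternatives were quantile normalization, removal of block means, of the first principal component or of the Y-linked mean, leaving out the 27 arrays, only genes above the median mean, the mean of all probes of a gene, Spearman correlation, odd and even blocks apart, random lists matched also on SD, principal component scores, stricter thresholds, pairs up to 10 genes apart, pairs of a family kept, all pairs of probes and a Kruskal-Wallis test. Alternatives added after the data were seen were animals above and below a gap in the Y-linked mean, block tests with the Y-linked mean, array correlation or clock scores as further terms, and leaving out 30 arrays with high pancreas or muscle scores. The adjustment for Xist was not made because no probe carried that symbol.

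The steps were tested on simulated data. Planted 1:2:1 genes were recovered in 0% of cases with adjacent means 1.5 SD apart, 1.16% at 2 SD and 87.3% at 3 SD, and 0.0667% of normal genes were called. Lists with a planted shared factor were recovered in 100% of cases. limma recovered 96.8% of genes whose block means had an SD of 0.5 within-block SD, and called 0.0851% of unchanged genes. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and data.table, version 1.17.8.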

Results

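Each of 294 mice from an F2 intercross of the strains B6/J and A/J contributed 1 liver array of normalized intensities. The labels form a single group and state no treatment, age or sex, so the comparisons here are between animals, between genes and between 15 label blocks of 17 to 23 animals whose meaning is not stated. The array medians lay between 21.1 and 23.2 intensity units. The median correlation of an array with the others was 0.989 over the arrays, with a lowest value of 0.974. The spread after ± is the SD over animals, and folds compare the 90th with the 10th percentile of the 294 animals unless stated otherwise.

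The first question was which liver genes differed most between F2 animals. The 15 widest are given among genes above the median mean, and some dimmer genes were wider than many of them. Hsd3b5, a ketosteroid reductase, spanned 431-fold with a mean of 6.94 ± 3.60 on the log2 scale (n = 294). Cyp2b13, a cytochrome P450, spanned 194.5-fold (8.83 ± 3.11), and Hao2, a peroxisomal hydroxy acid oxidase that the annotation lists as Hao3, spanned 142.2-fold (8.17 ± 2.75). The P450 gene Cyp2c39 spanned 106-fold (9.19 ± 2.50), and Slco1a1, a hepatic uptake transporter of organic anions, 69.4-fold (8.30 ± 2.35). Cyp3a44, a further P450, spanned 24.99-fold, the fatty acid elongase Elovl3 17.6-fold, the adipokine gene Serpina12 17.1-fold, and the steroid hydroxylase Cyp17a1 16.2-fold. The P450 genes Cyp2b9 and Cyp2d9 spanned 15.97-fold and 15.5-fold, and the zinc finger gene Zfp874a, listed as C330011K17Rik, 15.6-fold. The uncharacterised 9130409I23Rik, the magnesium transporter gene Nipal1 and the ion channel gene Asic5 completed the 15, at 14.02-fold, 13.8-fold and 12.5-fold. Background was not measured, and the 10th percentiles of Hsd3b5 (3.33 on the log2 scale), Cyp2b13 (4.37), Hao2 (3.71), Cyp3a44 (4.07) and Zfp874a (3.29) lay below every array median, so their folds are lower bounds. A range of at least 2-fold, 1 on the log2 scale, was found in 934 of 16643 genes (5.61%), while the median gene spanned 1.38-fold with an SD of 0.19 on the log2 scale.

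**Figure D1:**
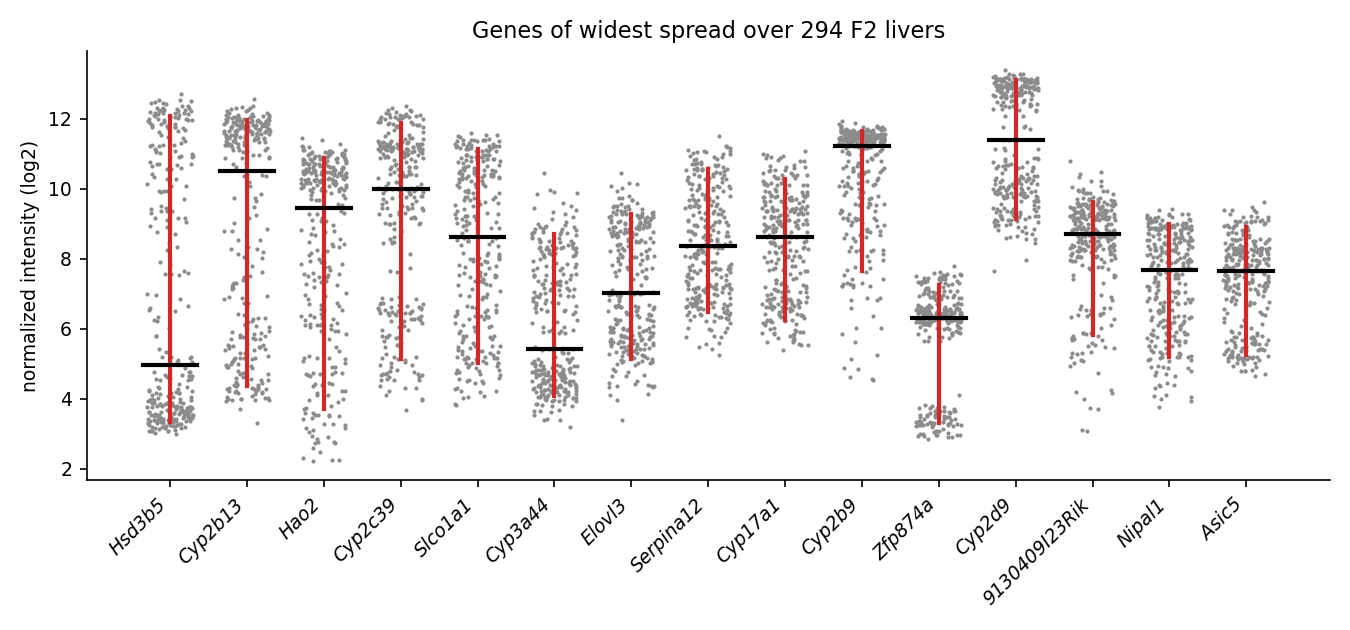
Normalized intensity (log2) of the 15 genes of widest range among those above the median mean, in the 294 livers, each dot an animal, the black bar the median and the red line the 10th to 90th percentile. Hsd3b5 spanned at least 431-fold and Asic5, the last of the 15, 12.5-fold.

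Y-linked genes divided the animals into separate clusters. Eif2s3y, a translation initiation factor gene, had no value between 3.03 and 6.97 on the log2 scale. The histone demethylase genes Kdm5d and Uty had none between 2.74 and 4.90 and between 2.97 and 4.97. These 3 genes placed the same 148 animals below the gap and the same others above it, and each label block held 7 to 12 animals above it. Lists of male-biased and of female-biased liver genes were clustered too. Of the widest genes named above, Hsd3b5, Cyp2d9, Slco1a1 and Elovl3 belong to the male-biased list. Cyp2b13, Cyp2b9, Cyp3a44 and Hao2 belong to the female-biased list. A mixture of 2 normals placed 45.8% of the weight of the male-biased score in its smaller class. In the female-biased score, only 8 of the 294 animals were on the same side in the score and in the Y-linked mean. With a linear fit on the Y-linked mean removed, the range of Hsd3b5 was 15.2-fold, of Cyp2b13 7.63-fold and of Cyp2d9 2.58-fold. Cyp2c39 kept 58.8-fold, Hao2 20.1-fold and Zfp874a 14.5-fold; the limit at low intensity named above holds here too. The first principal component over all genes carried 19.97% of the variance, and a pooled mean r of these 3 lists, given below, includes the distance between their clusters.

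The second question was whether genes of a known pathway or cell type varied together over the animals. A member's r below is with the mean z score of the other members of its list, and 416 such relations were computed. Unless given, the permutation p of both r and rho was 1e-05, the smallest that 100000 resamples can give, with an adjusted p of 1.34e-05 for r and 1.42e-05 for rho. Among the 36 lists with at least 3 measured genes, 30 had a higher mean pairwise r than random lists at an adjusted p under 0.05, and 23 of them reached the smallest p that 10000 random lists can give, 0.0001 (adjusted p = 0.000157). The 30 include the male-biased, female-biased and Y-linked lists, whose pooled values are given later beside those within the clusters. Leaving out the 2 animals farthest from the median score moved no named member's r by more than 0.0620 in the 34 lists other than pancreas, muscle and erythroid, and by up to 0.358 in pancreas, for Clps.

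Cholesterol synthesis was the most tightly varying metabolic pathway, with a mean pairwise r of 0.637 and all 19 measured genes positively correlated with the rest. Dhcr7, which encodes the last enzyme of the Kandutsch-Russell route, had r = 0.945 and rho = 0.948 and spanned 3.54-fold (n = 294). The isomerase gene Idi1 had r = 0.925 and rho = 0.915 and spanned 6.29-fold, and the sterol dehydrogenase gene Nsdhl r = 0.918 and rho = 0.916 with 4.05-fold. Srebf2, the master transcription factor gene of the pathway, was the loosest member at r = 0.426 and rho = 0.407 and spanned 1.38-fold. Fatty acid synthesis had a mean pairwise r of 0.441, and 16 of 17 genes were positively correlated with the rest. Acly, which makes cytosolic acetyl-CoA, had r = 0.881 and rho = 0.869, and fatty acid synthase, Fasn, had r = 0.880 and rho = 0.875 and spanned 3.01-fold. Mlxipl, which encodes the carbohydrate response factor ChREBP, was uncorrelated with them (r = -0.0145, rho = -0.112, adjusted permutation p = 0.817 and 0.06). In the list of fatty acid oxidation and PPARA targets the mean pairwise r was 0.380, and all 19 genes were positively correlated. Its closest members were the acyl-CoA thioesterase genes Acot2 (r = 0.842, rho = 0.844, 2.74-fold) and Acot1 (r = 0.815, rho = 0.753, 3.33-fold), and its loosest was the fatty acid binding protein gene Fabp1 (r = 0.152, rho = 0.105, adjusted permutation p = 0.0107 and 0.0822).

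Other hepatocyte functions were looser. Gluconeogenesis had a mean pairwise r of 0.158 (adjusted p = 0.0088), with 8 of 9 genes positively correlated, among them Igfbp1, an insulin-repressed secreted protein (r = 0.527, rho = 0.490, 5.14-fold), and Pck1, the rate-setting carboxykinase (r = 0.526, rho = 0.501, 2.33-fold). Periportal genes had 0.133 (adjusted p = 0.0269), with 5 of 8 genes positively correlated, led by the urea cycle genes Cps1 (r = 0.639, rho = 0.613) and Ass1 (r = 0.618, rho = 0.599); their call ended in odd blocks, at 0.118. Pericentral genes had 0.133 (adjusted p = 0.0072), with 8 of 9 genes positively correlated, among them glutamine synthetase, Glul (r = 0.367, rho = 0.367). Their mean pairwise r was 0.0853 above the Y-linked gap (adjusted p = 0.0445 against random lists) and 0.184 below it. Xenobiotic metabolism had 0.133 (adjusted p = 0.00135), with 12 of 16 genes positively and 2 negatively correlated over 286 animals. Its mean pairwise r was 0.203 above and 0.121 below the gap. Its Cyp2c29, a P450 gene, had r = 0.591 and rho = 0.580, and the aldehyde dehydrogenase gene Aldh1a7 had r = -0.292 and rho = -0.306. Lipoprotein genes (0.0618, adjusted p = 0.106), NRF2 targets (0.0608, adjusted p = 0.0796) and bile acid genes (0.0524, adjusted p = 0.136) did not exceed random lists over all animals, but above the Y-linked gap NRF2 targets (0.121, adjusted p = 0.00775) and bile acid genes (0.0967, adjusted p = 0.0324) did. Oxidative phosphorylation had 0.260 and cytosolic ribosome 0.313, although their genes varied little: Ndufv1, of respiratory complex I, spanned 1.17-fold (r = 0.690, rho = 0.70) and the ribosomal protein gene Rpl8 1.22-fold (r = 0.776, rho = 0.729). Positive correlations were found for 22 of 23 and 9 of 12 of their genes. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, had r = 0.986 and rho = 0.986 and spanned 3.94-fold and 8.66-fold, and were not tested as a list.

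Kupffer cell and MHC class II genes varied together more tightly than any tested metabolic list. Kupffer cell and macrophage genes had a mean pairwise r of 0.849, and all 17 were positively correlated without the 13 animals of the upper cluster. The complement genes C1qb (r = 0.967, rho = 0.969, 2.48-fold) and C1qc (r = 0.968, rho = 0.968, 2.50-fold) and the growth factor receptor gene Csf1r (r = 0.950, rho = 0.949, 2.14-fold) were among the 4 nearest to the list. MHC class II genes had 0.844 with all 7 genes positively correlated without the 18 animals of the upper cluster. The invariant chain gene Cd74 led them (r = 0.942, rho = 0.945) and spanned 3.30-fold over all 294 animals. Interferon response genes had 0.506 with all 25 positively correlated without the 16 animals of the upper cluster. Among them were Ifi44 (r = 0.836, rho = 0.847) and the guanylate binding protein gene Gbp3 (r = 0.875, rho = 0.866). Over all 294 animals Gbp3 spanned 4.38-fold. T and NK cell genes had 0.287 with 12 of 14 positively correlated, among them the chemokine gene Ccl5 (r = 0.598, rho = 0.588, without the 13 animals of its upper cluster). B and plasma cell genes had 0.196 (adjusted p = 0.0335), with 4 of 5 positively correlated. Their call ended in 5 alternatives, for example at 0.179 (adjusted p = 0.0528) without the 27 least correlated arrays. Acute phase genes had 0.366 with 19 of 21 positively correlated without the 11 animals of the upper cluster. Lcn2, an iron-sequestering protein of inflammation, spanned 10.8-fold (r = 0.634, rho = 0.595) and the serum amyloid gene Saa2 5.72-fold (r = 0.470, rho = 0.411), while the iron hormone gene Hamp was uncorrelated (r = -0.0419, rho = 0.105, adjusted permutation p = 0.498 and 0.0884).

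Stromal and stress lists also passed. Endothelial genes had a mean pairwise r of 0.494 with all 15 positively correlated, among them the sinusoidal lectin gene Clec4g (r = 0.769, rho = 0.789, without the 5 animals of the lower cluster). Stellate cell and fibroblast genes had 0.323 with all 14 positively correlated, led by the collagen genes Col1a2 (r = 0.858, rho = 0.847) and Col3a1 (r = 0.816, rho = 0.784, 2.37-fold). Cholangiocyte genes (0.0679, adjusted p = 0.383) and erythroid genes (0.0672, adjusted p = 0.134) did not exceed random lists over all animals, but erythroid genes did below the Y-linked gap (0.219, adjusted p = 0.00651). ER stress genes had 0.436 with 14 of 15 positively correlated without the 3 animals of the upper cluster, among them the chaperone gene Hspa5 (r = 0.898, rho = 0.880, 2.29-fold) and Creld2 (r = 0.874, rho = 0.853, 4.90-fold). The mean pairwise r of the ER stress genes was 0.480 above and 0.267 below the Y-linked gap. Heat shock genes had 0.382 with all 7 positively correlated, among them Hsph1 (r = 0.750, rho = 0.733, 2.29-fold) and Hspa1b (r = 0.618, rho = 0.613, 5.15-fold). Immediate early genes had 0.212 with 12 of 13 positively correlated, led by Fos (r = 0.753, rho = 0.747, 3.24-fold). Cell cycle genes had 0.349 with 13 of 15 positively correlated, led by the replicative helicase gene Mcm5 (r = 0.756, rho = 0.759, without the 7 animals of the upper cluster). Evening clock genes had 0.266, with 10 of 11 positively and 1, Bhlhe41, negatively correlated over 284 animals; the clock output genes Dbp (r = 0.636, rho = 0.634) and Tef (r = 0.624, rho = 0.601) were near the list. Morning clock genes had 0.220 (adjusted p = 0.0036), with 4 of 5 positively correlated, among them Arntl, the partner of CLOCK (r = 0.548, rho = 0.449).

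Markers of tissues other than liver were low in most animals and high in a few. Pancreas acinar genes had a mean pairwise r of 0.970, and 8 animals formed their upper cluster. The pancreatic lipase gene Pnlip reached 343.2-fold its median and the colipase gene Clps 360-fold, both lower bounds because their medians (2.89 and 2.30 on the log2 scale) lay below every array median. The 8 animals were all below the Y-linked gap, where the mean pairwise r was 0.984, against 0.420 above it. Skeletal muscle genes had 0.896 with 23 animals in the upper cluster, where muscle actin, Acta1, reached 56.3-fold its median. Without the 30 animals of either cluster, the mean pairwise r was 0.594 for pancreas and 0.467 for muscle. All 7 pancreas and all 6 muscle genes were positively correlated in the lower cluster. Neutrophil genes had 0.677, and 2 animals of 1 label block formed the upper cluster, with the calprotectin gene S100a8 at up to 129.2-fold its median. Both animals were among the 27 least correlated arrays, without which the mean pairwise r was 0.183 (adjusted p = 0.0509). Adipose genes had 0.189 (adjusted p = 0.0276), with 5 of 5 positively correlated, and their call ended in even blocks, at 0.160. Male-biased genes had 0.851, and 0.627 above and 0.255 below the Y-linked gap; Susd4 had r = 0.610 and rho = 0.540 in the lower cluster, and 8 of 8 genes were positively correlated. Female-biased genes had 0.653, and 0.367 above and 0.127 below the gap, with 6 of 8 positively correlated in the upper cluster. The Y-linked genes had 0.989, which was 0.0879 (adjusted p = 0.149) among the animals below the gap. The parental strain list had 0.0737 (adjusted p = 0.0732), and 0.0880 below the gap (adjusted p = 0.0316), with 3 of 6 positively correlated.

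**Figure D2:**
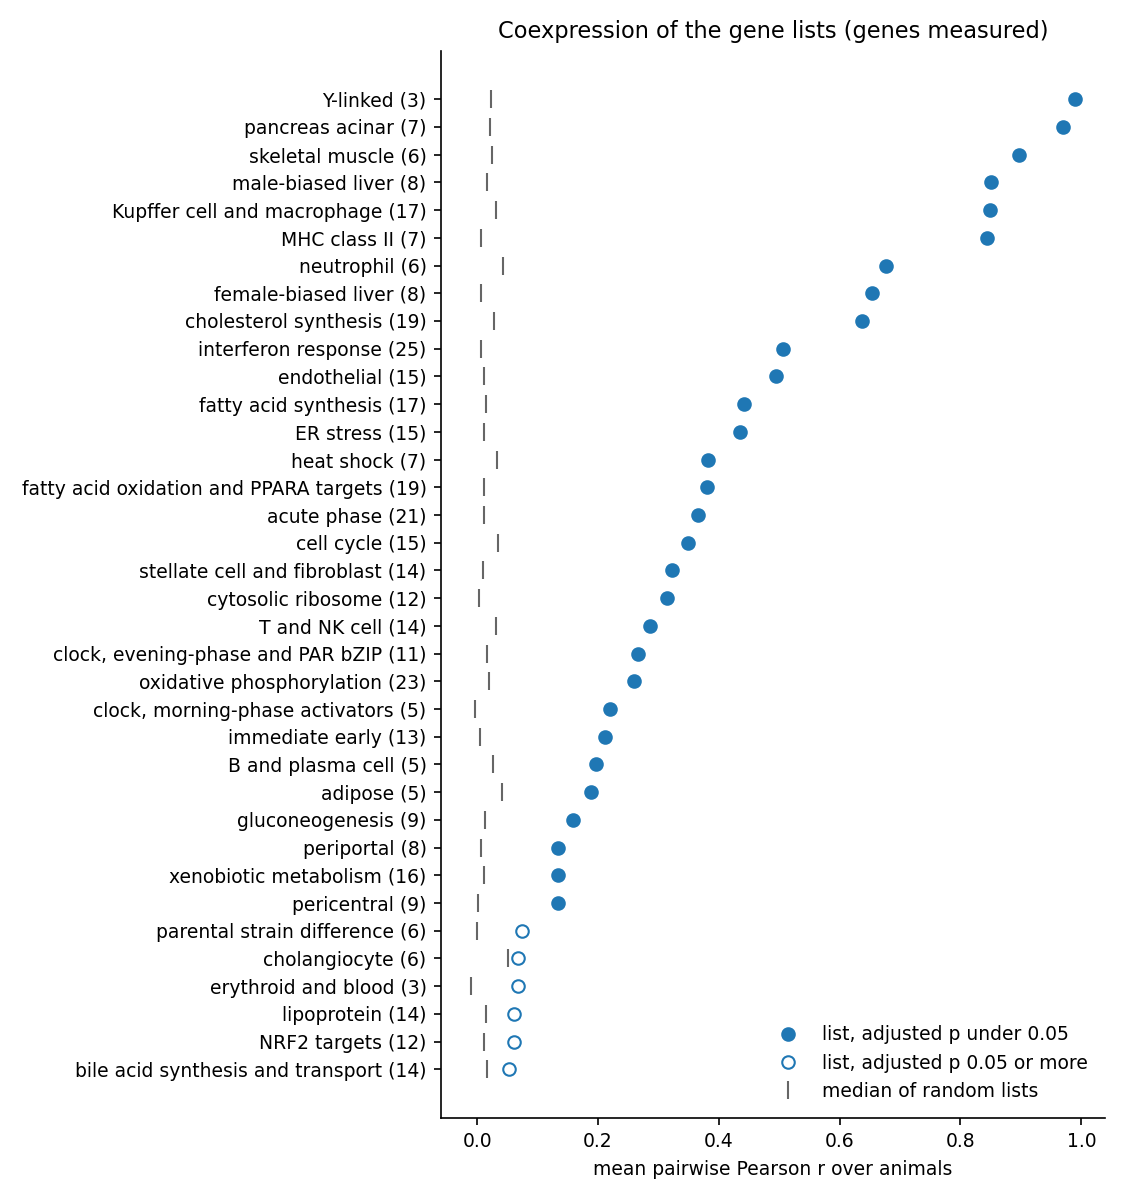
Mean pairwise Pearson r over the 294 animals for the 36 tested lists, with the number of measured genes in parentheses; filled dots have an adjusted p under 0.05, open dots do not, and ticks mark the median of random lists. The Y-linked list has the highest value, 0.989, which includes the distance between its clusters, and the bile acid list the lowest, 0.0524.

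Animals with high cholesterol synthesis genes had high fatty acid synthesis genes (r = 0.526, rho = 0.529, n = 294, adjusted permutation p = 1.8e-05 for each), with a positive r in 15 of 15 label blocks, and r was 0.646 above and 0.745 below the Y-linked gap. They had low fatty acid oxidation and PPARA target genes (r = -0.433, rho = -0.421, adjusted permutation p = 1.8e-05 for each), with a negative r in 15 of 15 blocks, and r was -0.258 above the gap (adjusted p = 0.00249) and -0.404 below it. Fatty acid synthesis was not related to oxidation over all animals (r = -0.0685, rho = -0.0694, adjusted permutation p = 0.272 and 0.265), but r was -0.378 among the 148 animals below the Y-linked gap (adjusted p = 3.6e-05) and 0.0341 among the others (adjusted p = 0.683). A difference between these values was not tested. Fatty acid synthesis and gluconeogenesis had r = 0.0340 and rho = 0.0310 (adjusted permutation p = 0.595 and 0.596). Cholesterol synthesis and bile acid genes had r = -0.0242 and rho = -0.0363 over 288 animals (adjusted permutation p = 0.685 and 0.572), with r = -0.184 (adjusted p = 0.00212) once the Y-linked mean was removed. Their r was -0.163 above and -0.163 below the Y-linked gap, called in neither (adjusted permutation p = 0.0714 and 0.0606). ER stress with cholesterol synthesis had r = 0.143 and rho = 0.180 without the 3 animals of high ER stress score (adjusted permutation p = 0.0195 and 0.00283), but r was -0.0968 above and -0.0759 below the Y-linked gap (adjusted p = 0.298 and 0.361), so the pooled relation did not hold within the clusters.

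**Figure D3:**
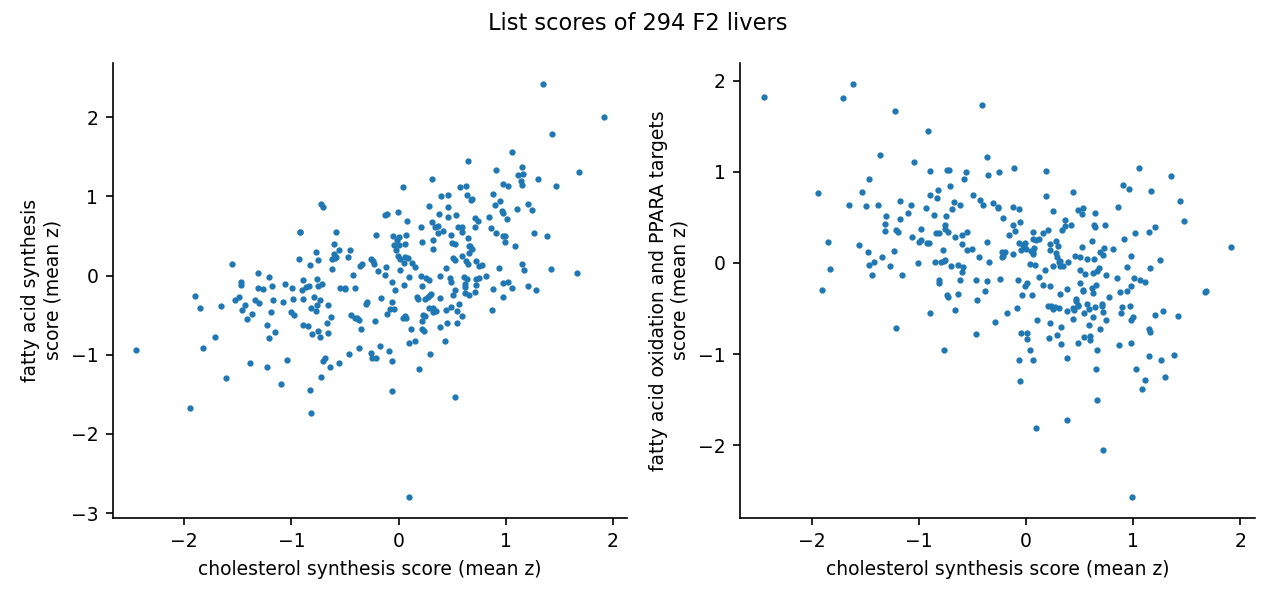
Scores (mean z) of the 294 livers for cholesterol synthesis against fatty acid synthesis (left) and against fatty acid oxidation and PPARA targets (right), each dot an animal. The left relation has r = 0.526 and the right r = -0.433.

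Immune and stromal scores varied together between animals. Within the largest cluster of each pair of scores, Kupffer cell genes were related to MHC class II genes (r = 0.719, rho = 0.697), stellate cell genes (r = 0.557, rho = 0.568), T and NK cell genes (r = 0.472, rho = 0.461) and cell cycle genes (r = 0.409, rho = 0.419). Interferon response was related to MHC class II (r = 0.489, rho = 0.473, n = 268) and to acute phase (r = 0.428, rho = 0.462, n = 270). Acute phase genes were inversely related to cholesterol synthesis (r = -0.416, rho = -0.370, without the 11 animals of high acute phase score). Morning and evening clock genes were inversely related (r = -0.416, rho = -0.387, n = 284). The adjusted permutation p was 1.8e-05 for r and rho in each of these 8 relations, and the sign was the same in 15 of 15 label blocks for 5 of them, in 14 for acute phase with interferon and with cholesterol synthesis, and in 13 for Kupffer with T and NK cells. Taken above and below the Y-linked gap apart, several of the 8 were weaker. Kupffer with cell cycle genes had r = 0.273 and 0.218 (adjusted p = 0.00189 and 0.0153), with stellate cell genes 0.421 and 0.372, with T and NK cell genes 0.393 and 0.388, and with MHC class II 0.762 and 0.619. Interferon with MHC class II had 0.538 above and 0.224 below (adjusted p = 3e-05 and 0.0144), and with acute phase 0.317 and 0.304. Acute phase with cholesterol synthesis had -0.406 and -0.186 (adjusted p = 5.14e-05 and 0.0338), and morning with evening clock genes -0.398 and -0.315. Immediate early and heat shock genes had r = 0.267 and rho = 0.215 over 294 animals (adjusted permutation p = 3.27e-05 and 0.000524), positive in 10 of 15 blocks. Acute phase with xenobiotic metabolism was at the margin (r = -0.127, rho = -0.109, n = 280, adjusted permutation p = 0.0427 and 0.0882), and its call ended without the 30 arrays of high pancreas or muscle score (r = -0.116, adjusted p = 0.0852), but r was -0.285 above and -0.326 below the Y-linked gap (adjusted p = 0.00132 and 0.00018). Pericentral and periportal genes had r = -0.0820 and rho = -0.115 (adjusted permutation p = 0.193 and 0.0679). Male-biased with female-biased genes had r = -0.221 and rho = -0.0990 in the largest cluster (adjusted permutation p = 0.00901 and 0.265) and r = -0.786 and rho = -0.815 in the next largest (adjusted permutation p = 3e-05 for each). In all, 14 of the 18 relations had an adjusted p under 0.05. Leaving out the 2 animals farthest from the median kept each of their signs, with the lowest size left at -0.116 for acute phase with xenobiotic metabolism and at 0.123 for ER stress with cholesterol synthesis.

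For 5 of the scores, genes outside that score's own list followed it (Acss2, Pgd, Lcat and Arntl belong to other lists), and since the genes were chosen as the most correlated of all genes, the r and rho given next are descriptive and no p is given for them. Cholesterol synthesis was followed by the retinol dehydrogenase gene Rdh11 (r = 0.905, rho = 0.915, n = 294), the acetyl-CoA synthetase gene Acss2 (r = 0.856, rho = 0.875) and the mitochondrial citrate carrier gene Slc25a1 (r = 0.853, rho = 0.848), and inversely by Lcat, which esterifies plasma cholesterol (r = -0.598, rho = -0.615). Fatty acid synthesis was followed by the pentose phosphate gene Pgd (r = 0.807, rho = 0.806), the water channel gene Aqp8 (r = 0.781, rho = 0.754) and the acyl-CoA synthetase gene Acsl5 (r = 0.776, rho = 0.762), and inversely by the plasma protein gene Hrg (r = -0.616, rho = -0.641). The acute phase score was followed by Stat3, the transcription factor of interleukin 6 signalling (r = 0.707, rho = 0.702, without the 11 animals of high score), and by Serpina10, which encodes the protein Z-dependent protease inhibitor (r = 0.682, rho = 0.644), and inversely by the carbonic anhydrase gene Car3 (r = -0.565, rho = -0.567). The interferon score was followed by Rtp4 (r = 0.886, rho = 0.894, without the 16 animals of high score), Shisa5 (r = 0.810, rho = 0.810) and the ubiquitin ligase gene Rnf213 (r = 0.787, rho = 0.788), and inversely by the epoxide hydrolase gene Ephx2 (r = -0.490, rho = -0.496). The evening clock score was followed by the coactivator gene Ppargc1b (r = 0.580, rho = 0.563, n = 284), the triglyceride synthesis gene Dgat2 (r = 0.520, rho = 0.495) and the cell cycle kinase gene Wee1 (r = 0.507, rho = 0.506), and inversely by the morning gene Arntl (r = -0.513, rho = -0.498). Taken above and below the Y-linked gap apart, several of the inverse values were weaker. Ephx2 had r = -0.276 and -0.227, Lcat -0.457 and -0.455, and Car3 -0.456 and -0.414. Arntl had -0.489 and -0.470, and Hrg -0.606 and -0.661.

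The third question was which genes took values in separate classes, since an intercross of inbred strains yields genotypes in the ratio 1:2:1 at each autosomal locus. A mixture of 3 equally spaced normals with weights 1:2:1 was called for 19 of 16643 genes (0.114%), with a median fold of 2.23 between the outer means. In simulated data the call recovered 1.16% of planted genes at a spacing of 2 SD and 87.3% at 3 SD. Classes closer together are therefore mostly missed. Adi1, an enzyme of the methionine salvage pathway, had the strongest call, with fitted means of 9.85, 10.41 and 10.97 on the log2 scale. Bcl6, a transcriptional repressor, had the widest outer means of the 19, 7.36-fold apart, followed by D630033O11Rik at 4.68-fold. The histone demethylase gene Kdm2b (2.46-fold), the sugar transporter gene Slc35d2 (2.53-fold) and Chtf8, a subunit of the clamp loader of sister chromatid cohesion (2.69-fold), came next in width among the 13 called genes above the median mean. Saraf, a regulator of calcium entry listed as Tmem66 (1.83-fold), the lipid kinase gene Pi4kb (1.79-fold), Bckdhb of branched-chain amino acid breakdown (1.70-fold), the DNA glycosylase gene Mpg (1.92-fold), the amino acid transporter gene Slc38a6 (2.07-fold), the mitochondrial protease gene Yme1l1 (1.71-fold) and the kinase gene Slk (1.91-fold) were the others. With block means removed, 8 of the 19 kept the call, while Adi1, Saraf and Slc35d2 were called 1:3 and Bcl6, Chtf8, D630033O11Rik and Yme1l1 had no call. All 5 of the genes named here with several probes, Pi4kb, Bcl6, Mpg, Yme1l1 and Slk, had no call with the mean of all their probes, and Bcl6 and Yme1l1 had none with the Y-linked mean removed. At a BIC gain over 30 only 3 passed, Adi1, Saraf and Kdm2b. A mixture of 2 normals in the ratio 1:3 was called for 0.871% of genes.

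Among genes known to differ between the parental strains, Hc, which encodes complement C5, was called 1:3 (11.18 ± 0.92), as were Nnt, the mitochondrial transhydrogenase (10.18 ± 0.53), and Glo1, the detoxifying glyoxalase (11.89 ± 0.51). With free spacing, the 3 means were 9.79, 11.45 and 12.11 for Hc, 9.26, 10.24 and 10.76 for Nnt, and 11.08, 12.01 and 12.42 for Glo1. H2-Ea (5.41 ± 0.77), Dysf (3.39 ± 0.33) and Naip5 (2.93 ± 0.31) had no call. The 90th percentiles of Dysf (3.81) and Naip5 (3.27) lay below every array median. At such low intensity the lack of a call does not show that these 2 genes lack separate classes. With free spacing 62 genes were called 1:2:1, with outer means a median of 3.14-fold apart and 15 of them among the 19. Some low means, such as those of Zfp874a and Trim12a at 10.3 and 8.45 intensity units, lay below every array median. The folds of such genes are lower bounds.

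**Figure D4:**
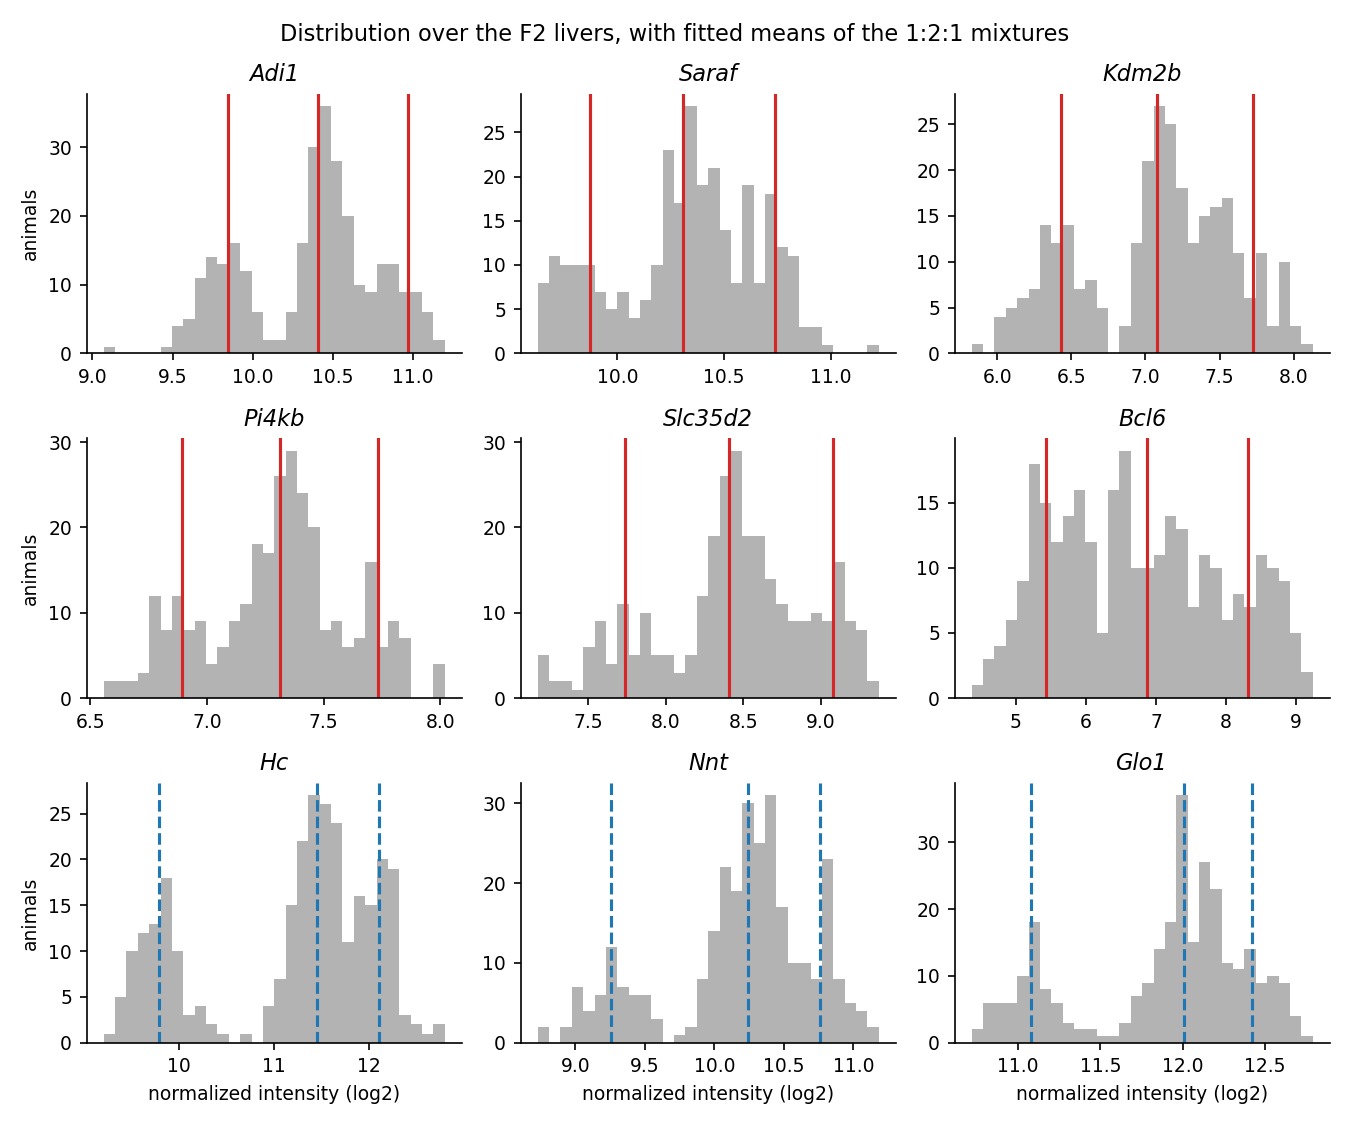
Histograms of log2 intensity over the 294 animals for the 6 strongest 1:2:1 genes, with red lines at the fitted means, and for Hc, Nnt and Glo1, with blue dashed lines at the means of the mixture with free spacing. The means of Hc lie at 9.79, 11.45 and 12.11.

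Genes next to each other on a chromosome varied together slightly more than genes on different chromosomes. The metallothionein genes Mt1 and Mt2 had r = 0.986 and rho = 0.986 over 294 animals. The complement genes C8a and C8b had r = 0.822 and rho = 0.822 in the larger cluster of animals and r = 0.758 and rho = 0.744 in the other. Snrnp25, of the minor spliceosome, and Rhbdf1, a regulator of growth factor shedding, had r = 0.814 and rho = 0.744 in the largest cluster and r = 0.422 and rho = 0.280 in a cluster of 67. The macrophage genes Sdc3 and Laptm5 had r = 0.839 and rho = 0.841 in the largest cluster. The laminin gene Lama3 and Ttc39c had r = 0.686 and rho = 0.694 in the next largest cluster and r = 0.140 and rho = 0.123 in the largest. Kdm5d and Eif2s3y had r = 0.532 and rho = 0.512 over the animals above the gap and r = 0.0266 and rho = 0.0406 over the 148 below it. These 6 pairs were chosen as the adjacent pairs of highest absolute r, so their values are descriptive and no p is given for them. Over 15312 adjacent pairs the median absolute r was 0.110, against 0.0963 for pairs on different chromosomes, and no permutation of positions exceeded 0.0990 (p = 0.001, the smallest that 1000 permutations can give). For 5 pairs of 1:2:1 genes that follow each other on a chromosome within that set, but are over 100 genes apart, it was 0.386 against 0.0565 (p = 0.001). These are medians over gene pairs, which are not independent replicates.

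Expression also differed between label blocks. The coagulation factor gene F9 had 43.01% of its variance between blocks and differed 1.69-fold between the lowest and the highest block (adjusted p = 6.19e-23, limma). Eif3e, a translation initiation factor gene, had 42.2% and differed 1.35-fold between the extreme blocks. Rab5c, a GTPase of early endosomes, had 41.5% and differed 3.03-fold. The other genes of largest share were Thoc2 of mRNA export (41.2%, 1.88-fold), Evi5 (41.2%, 1.59-fold), the calcium pump gene Atp2b1 (40.9%, 1.80-fold), the bile acid uptake transporter gene Slco1b2 (40.7%, 1.80-fold) and the chromatin regulator Ankrd11 (40.5%, 1.35-fold). In all, 5436 of 16643 genes differed between blocks at an adjusted p under 0.05 (limma), and 6866 at an unadjusted p under 0.05. All 7 heat shock, 6 muscle and 6 neutrophil genes differed, over all genes and adjusted over the list alone, but by the Kruskal-Wallis test, which is less moved by a few outlying arrays, 7, 2 and 3 did. Cholesterol synthesis had 15 of 19 genes, and 18 adjusted over the list alone. Fatty acid synthesis had 14 of 17 by either count, oxidative phosphorylation 14 of 23 and 17 adjusted over the list alone, evening clock genes 8 of 11 by either count, and morning clock genes 4 of 5 and 5 adjusted over the list alone. Acute phase had 11 of 21 and 12 adjusted over the list alone. Bright genes were called more often, with 4954 of 8321 when only genes above the median mean were tested. Against random lists of like mean, the median variance share between blocks lay at percentile 76.4 for cholesterol synthesis and 61.5 for fatty acid synthesis. The percentile was 50.9 for oxidative phosphorylation, 27.5 for acute phase, 89.85 for evening and 96.2 for morning clock genes. Except for morning clock genes, the counts do not set these lists apart from genes of like mean. The Kruskal-Wallis test called 14 cholesterol synthesis, 12 fatty acid synthesis, 14 oxidative phosphorylation, 6 evening clock, 2 morning clock and 8 acute phase genes. By limma 0 of 17 Kupffer cell and 0 of 14 T and NK cell genes differed, over all genes and adjusted over the list alone, with 2 and 1 at an unadjusted p under 0.05 and 0 by the Kruskal-Wallis test. In the MHC class II, male-biased, Y-linked, pancreas and parental strain lists, limma called 0 genes by either count, with 0 at an unadjusted p under 0.05 and 0 by the Kruskal-Wallis test. These tests held no Y-linked term. For the male-biased and Y-linked genes the distance between the clusters therefore counts as spread within blocks, which can hide differences between blocks. The heat shock score had 27.6% of its variance between blocks, the muscle score 16.2% and the fatty acid synthesis score 15.3%, against 1.35% for the Y-linked score. The variance of the Y-linked score includes the distance between its clusters.

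**Figure D5:**
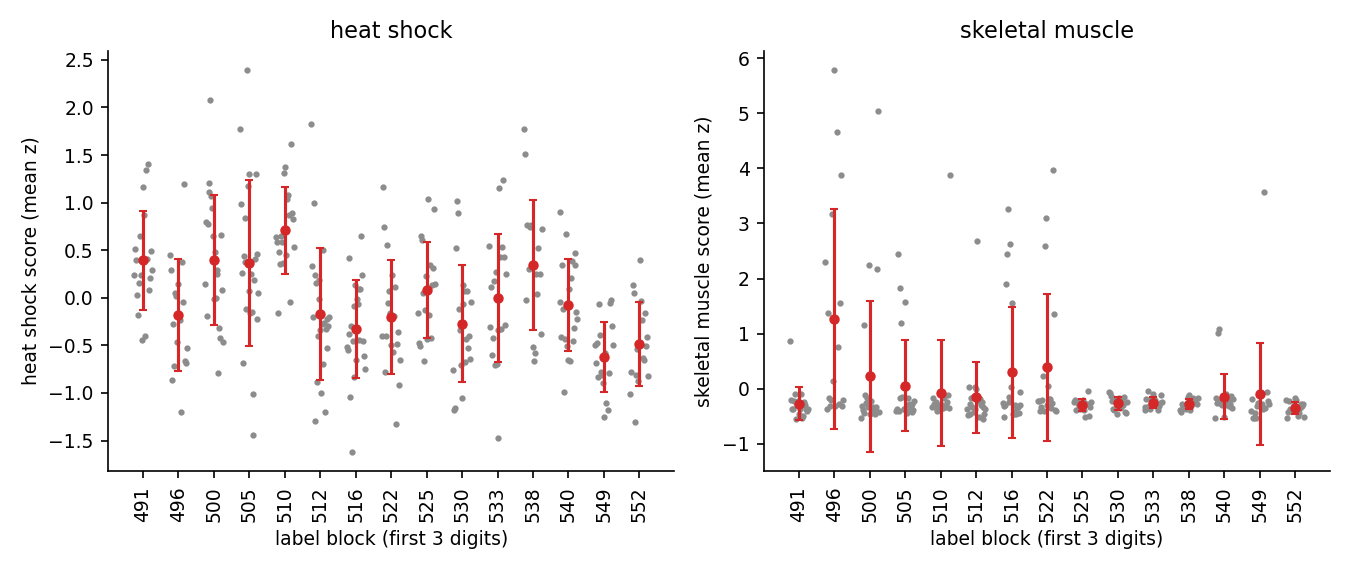
Heat shock and skeletal muscle scores (mean z) of the animals in each of the 15 label blocks, with each dot an animal and the red points and bars the mean and SD of a block. Between blocks lay 27.6% of the variance of the heat shock score and 16.2% of that of the muscle score.

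Probes of the same gene gave a check on measurement error. Among genes of 1:2:1 shape the 2 brightest probes had a median r of 0.712 over 6 genes, with Bcl6 at 0.768, Slk at 0.866, Pi4kb at 0.164 and Mpg at -0.0852. For Glo1 the probes had r = 0.906 and for Nnt r = 0.948, although the second Glo1 probe had no shape call and the second Nnt probe was called 1:3 also with free spacing. Over 5825 genes with at least 2 probes the median r between the 2 brightest was 0.297, and 34.7% of genes exceeded 0.5 (95% Wilson interval 33.5 to 35.9). Among 3729 genes above the median mean the share was 50.1%.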

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

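The settings with animals above or below the Y-linked gap, free spacing, further block terms or the 30 arrays of high pancreas or muscle score left out were chosen only after the data were seen. Of 810 alternative values for 63 results, 759 were counted as the same and 51 were not. For a correlation this meant that its call and direction stayed, and for a count or share that it stayed within the allowed range. Where neither value was called, a change of sign also counted as the same. Fatty acid synthesis with gluconeogenesis, for example, had r = 0.0340 over all animals and -0.149 below the gap. The count of lists ranged from 21 to 32, of relations from 12 to 15, and of genes differing between blocks from 4628 to 6364, of which 4493 to 5422 were shared with the reported ones. In the alternatives run, 27 of 36 lists and 12 of 18 relations kept their call throughout. With the first principal component removed, the mean r was 0.0960 for NRF2 targets, 0.126 for erythroid and 0.0815 for parental strain genes, all newly called, and 0.152 for B cells, no longer called. With the Y-linked mean removed it was 0.0799 for bile acids, 0.0956 for NRF2 targets, 0.133 for erythroid and 0.0803 for parental strain genes, newly called, 0.164 for B cells, no longer called, and -0.489 for the Y-linked genes, whose own mean was removed. Above the gap bile acids had 0.0967 and NRF2 targets 0.121, newly called, and B cells 0.107, not called. Below it erythroid genes had 0.219 and parental strain genes 0.0880, newly called, and Y-linked genes 0.0879, not called. Without the 27 least correlated arrays B cells had 0.179 and neutrophils 0.183, not called. Even blocks gave 0.0868 for NRF2 targets, newly called, and 0.153 for neutrophils and 0.160 for adipose genes, not called. Odd blocks gave 0.118 for periportal genes, not called, and 0.103 for parental strain genes, newly called. Spearman correlation gave 0.145 for B cells, not called. For fatty acid synthesis with oxidation, r was -0.167 without the first component, -0.138 without the Y-linked mean and -0.378 below the gap, all newly called. Cholesterol synthesis with bile acids had -0.160 and -0.184 under the same removals, newly called, and 0.412 with principal component scores, reversed. Acute phase with xenobiotic metabolism had -0.0415 in even blocks, -0.116 without the 30 arrays and -0.109 by Spearman, not called, and 0.276 with component scores, reversed. Pericentral with periportal had -0.136 without the 27 arrays, newly called. ER stress with cholesterol synthesis reversed to -0.106 without the first component, -0.0800 without the Y-linked mean, -0.0968 above and -0.0759 below the gap, and had 0.0167 in odd blocks, not called. Male-biased with female-biased genes had -0.148 in even blocks, -0.271 over the 6 animals of the cluster above the gap and -0.0990 by Spearman, not called. Counts moved for variable genes (611 with an SD of at least 0.5), for 1:2:1 genes (9 without block means, 8 of them shared, 62 with free spacing, and 3 at a BIC gain over 30) and for 1:3 genes (58 at that gain). The share of genes with probes over 0.5 was 32.2% without the 27 arrays, 50.1% above the median mean and 28.4% over all probe pairs. The cause was not tested, except that stricter thresholds by construction call less. The adjustment for Xist was not run, since no probe carried that symbol. No paired analysis was possible because each animal gave a single array. Signal over background may limit the dim genes, but background was not measured. The r between probes exceeded 0.5 in 50.1% of genes above the median mean, against 34.7% over all genes. Median absolute r of adjacent genes ranged from 0.102 to 0.169.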

Other observations

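The fits with free spacing and all tests on them, the position of the middle mean, the interval of the median r between probes, the block tests with further terms, and the tests on the 30 arrays of high pancreas or muscle score and on each part of them were chosen only after other results had been seen.

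Beyond the genes named so far, several liver genes stayed wide once a fit on the Y-linked mean was removed. Nnmt, which methylates nicotinamide, spanned 10.1-fold, the signalling adaptor gene Pik3ap1 10.4-fold, and the immediate early gene Egr1 7.72-fold between the 10th and 90th percentiles (n = 294). Among the 7132 probes with no symbol, 190 (2.66%) spanned at least 2-fold. The mixture with free spacing described 62 genes, with Zfp874a at fitted means of 10.3, 80.5 and 150 intensity units, Snrnp25 at 69.99, 300.8 and 534, and Hc at 888, 2803 and 4436. On this linear scale the middle mean lay a median of 49.7% of the way from the low to the high mean (quartiles 46.8% and 51.4%, from 28.5% to 58.9%), and within 40 to 60% in 54 of the 62 genes. A call needs both steps to be wide, so genes whose middle class equals an outer one are not among them.

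Genes of 1:2:1 shape numbered 19 with equal spacing and 66 with free or equal spacing. A sequence variant under the probe, which could alter binding and not expression, cannot be told apart: the median r between the 2 brightest probes was 0.712 over 6 genes of the 19 (95% interval of the median -0.0852 to 0.866) and 0.807 over 20 of the 66 (0.442 to 0.907), so neither interval clears the bound of 0.5. Mpg, Pi4kb, Pik3ap1 and Trim12a lay below 0.2, the 5 genes of the 19 named with several probes had no call with the mean of their probes, and most of the genes have a single probe. Differences between label blocks are argued against for the 66, of which 77.3% kept the shape without block means, and cannot be told apart for the 19, of which 42.1% kept it, between the bounds set in advance. Genotype at a linked locus is a candidate explanation: the median absolute r exceeded that of pairs on different chromosomes by 0.330 for 5 pairs of the 19 that follow each other within that set, over 100 genes apart, and by 0.701 for 15 pairs of the 66 up to 50 genes apart, and it went from 0.750 there to 0.759 (8 pairs), 0.581 (28 pairs up to 200 genes apart), 0.407 (32 pairs up to 400) and 0.144 (18 pairs beyond). Genotypes were not analysed here and the labels give no group that differs in them, so the test along chromosomes is indirect and no biological explanation was tested between groups.

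Of 100 splits of the animals into blocks of the same sizes, 1, the real one, gave as many as the 5436 genes that differed between label blocks, and the highest other gave 2, so chance can be excluded. Uneven Y-linked clusters are argued against as the whole cause. With the Y-linked mean as a further term 6364 genes passed, 5422 of them shared with the 5436. With the array correlation 5203 genes passed and with both clock scores 5496 (4965 and 4823 shared), also above the bound set for them. A linear term for a summary measure need not remove all of an effect of array quality or time of day. These counts therefore cannot decide on either as the whole cause. Time of day of collection may contribute: the clock genes had a median of 12.4% of variance between blocks, at percentile 98.3 of random lists of like mean. That test is not specific, because lists other than the clock genes, heat shock (19.99%), muscle (16.2%), neutrophil (9.92%) and cell cycle (7.05%), also exceeded the 95th percentile of their random lists, whose genes are less correlated with each other. What the blocks stand for is not stated, so litter, handling and array processing stay open, and no biological explanation was tested between groups. Each block covered its own run of F2 numbers in the titles, so block cannot be told apart from the order of those numbers.

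Pancreas acinar genes were high in 8 arrays from 6 label blocks and skeletal muscle genes in 23 arrays from 8 blocks, 30 arrays in all. All 8 of the first lay below the Y-linked gap and 10 of the second above it, and why the 8 did was not tested. Low array quality was measured here only as low correlation with the other arrays, and no other quality measure was examined. In that sense it is argued against for the muscle arrays, of which 1 of 23 was among the 27 least correlated arrays. It is likewise argued against as the cause for the 30 together, of which 3 were (10%, against 9.18% of all arrays). For the pancreas arrays alone 2 of 8 were, which is not under the bound set for the 30 together. The bounds for each part were written only after the data were seen. With so few arrays, low quality cannot be told apart for the pancreas arrays. Pancreas tissue carried over with the liver may account for the first: 11 further acinar genes, written down before the test, had a median of 8 of their 8 highest arrays among the same 8 (5 to 8), with Reg1 at up to 76.9-fold and Cela3b at up to 68.9-fold its median (lower bounds, as both medians lay below every array median), and 1 of the 11, Cela1, had a median above that of all genes. Muscle carried over may account for the second: 16 further muscle genes had a median of 18.5 of their 23 highest arrays among the same 23 (5 to 22), with Tnnc2 at up to 48.7-fold and Myh1 at up to 38.1-fold its median (lower bounds likewise), and 1 of the 16, Tpm2, had a median above that of all genes. The labels describe no dissection that would remove either tissue, expression of these genes by the liver itself stays open, and no biological explanation was tested.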
